A study of Arabidopsis thaliana with 60 samples.

How the data were processed

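Adult leaves were sampled as 2 leaves per plant and 2 plants per library, and treated 3 to 4 h after subjective dawn, per the labels' protocols. Libraries were made with Smart-3SEQ, in which each read begins with a 5-base molecular identifier. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, 8 bases were trimmed and reads were aligned to TAIR10 with STAR 2.4.2a by the authors before deposit. The deposited table holds raw counts of 25036 genes in 60 libraries. The counting tool, the annotation, the use of strand and whether duplicate identifiers were collapsed are not given in the sources used here, so a count may be a read or a molecule. No fastq file was processed again.

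Gene symbols came from the TAIR10.1 annotation, which matched 24888 genes (99.4%). The build differs from that of the authors, so names were used and coordinates were not. Overlapping and antisense genes and close copies may share tags.

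Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 16763. Counts were scaled with TMM factors (0.803 to 1.15) and tested with edgeR's quasi-likelihood F test, with all 60 libraries and 20 groups in 1 fit, no replicate block and 40 residual degrees of freedom. The p values were adjusted by Benjamini and Hochberg over genes within each contrast, with 0.05 as the threshold. The model, the comparisons, the lists and most of the alternatives were fixed from the labels before the data were examined. Adjusted p values in the text are from this edgeR test unless another tool is named, and the list tests are from camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over lists and times within a comparison. In the list tests "adjusted over the list alone" means an adjustment over the members of 1 list.

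The 23 lists held 384 entries and 370 genes, of which 341 were tested and 14 were in more than 1 list. They were written from general knowledge of the genes. Named genes were chosen by rule as the 3 largest rises and falls per comparison and time with at least 5 CPM in 1 group, an adjusted p under the threshold and the same direction in all 3 experiments. A fixed set (FRK1, PR1, WRKY33, PAD3, FMO1, EDS1, PAD4, ICS1, AOS, EIN2, RIN4 and RPS2) was always examined, and list members were added as examples. For those examples, members whose call held when any 1 library was left out were preferred, so they are more stable than their lists.

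Log2 CPM used a prior count of 2 with 0.5 and 5 as alternatives. For the effect of 1 elicitor with minus without the other, genes were chosen by the mean effect, signed by its direction, and the median was taken within each experiment. Choosing by the mean effect leaves out most genes with a strong interaction. The sign-flip test over experiments is exact.

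The pipeline was tested on simulated data over 16091 genes, with rates not split by count. Between 2 groups it called 33% of 2-fold and 81.2% of 4-fold changes, and 4.35% of calls were unchanged genes. For the interaction it called 8.08% of 2-fold and 84.8% of 8-fold effects, with 6.12% of calls unchanged. Camera gave p = 8.03e-31 for 30 genes raised 1.7-fold and 0.201 for an unchanged list, with correlated lists untested. The effect difference was -1.02 over 86 chosen genes simulated at -1, a narrowing made after the first result was seen, and -1.07 over all 92 chosen genes. Only 6 of 100 genes simulated at -3 were chosen.

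Libraries were checked for depth, chloroplast share (3.13 to 6.4%), mitochondrial share (0.0184 to 0.0725%) and the share of the 10 highest genes (5.07 to 13%). Spearman correlations across genes between the 60 pairs of replicates lay between 0.822 and 0.981, and 0 pairs were identical. Pairing by experiment was checked as the correlation across genes of residuals, with a median of 0.121 between libraries of 1 experiment and -0.0801 between experiments, and 50 of 90 pairs above 0.1. The fit without a block had been fixed before, so a block by experiment was an alternative. No library was left out of the results unless stated. The 4 libraries of experiment 2 were found from clock genes after the data were examined, and their labels were neither changed nor used as exchanged.

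Alternatives were a replicate block, RLE factors, library sizes alone, no filter, a filter of 10 CPM in 3 samples, DESeq2 1.42.0, limma-voom, only the groups compared, each experiment or library left out, an estimated correlation, fry, and, added later, fits without the 4 libraries, without the untouched libraries of experiment 3 and with Mock libraries not shared. Other splits of the libraries were drawn 60 times and overlap simulations 20 times, numbers lowered from 100 and 30 after the first run proved slow.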

Results

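Transcript abundance was measured by Smart-3SEQ, a 3′-end RNA sequencing method, in adult leaves of an Arabidopsis thaliana line of the Col-0 ecotype that carries mutations in DDE2, EIN2 (AT5G03280), PAD4 (AT3G52430) and SID2 and an estradiol-inducible transgene for AvrRpt2. DDE2 is the jasmonate synthesis gene AOS (AT5G42650), EIN2 transduces ethylene signals, PAD4 is a lipase-like regulator of defence, and SID2 is the salicylic acid synthesis gene ICS1. AvrRpt2 is a bacterial protease that cleaves the host protein RIN4 (AT3G25070), which the resistance protein RPS2 (AT4G26090) senses, and flg22 is a flagellin peptide sensed by the receptor kinase FLS2 (AT5G46330). Leaves were infiltrated with 0.1% ethanol (Mock), 1 µM flg22, 10 µM estradiol in 0.1% ethanol (Ed), or flg22 and Ed in one solution, and were collected after 60, 120, 180 or 300 min. No ethanol is listed for the flg22 solution, so comparisons of flg22 leaves, and the interaction, may differ in it too. Leaves labelled 0 min were untouched. The 60 libraries formed 20 groups of 3, and each group held 1 library from each of 3 independent experiments according to the design text. Library totals ranged from 1.46 to 4.67 M counts with a median of 3.52 M. In each library between 17646 and 19484 genes had at least 1 count, and 3 counts corresponded to 0.642 to 2.06 counts per M (CPM).

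Log2 fold changes are given ± a value worked back from the F statistic, not an estimated standard error. Groups held 3 libraries (12 untouched ones where Mock was set against them). CPM are given ± SD. Every named gene given as rising or falling did so in all 3 experiments unless another number is given. Where a group had 0 counts the fold is a lower bound against 3 counts over its libraries, and where it had 1 to 3 counts the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only. List tests were run with camera at a preset correlation, and an adjusted p with an estimated correlation stands beside each call that it ended.

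Clock genes set 4 libraries of experiment 2 apart from the others with the same label. LHY (AT1G01060), a morning-expressed clock regulator, stood at 106 CPM in the library labelled Mock 0 min of experiment 2, at 250 CPM in the one labelled Mock 60 min, at 316 CPM in the one labelled Mock 300 min and at 4.65 CPM in the one labelled flg22 0 min. In experiment 1 the same labels gave 284, 158, 3.07 and 268 CPM. Across the 20 clock genes, which are not independent replicates, the library labelled Mock 0 min correlated at 0.97 with Mock 60 min leaves of the other experiments and at 0.37 with untouched leaves. For the library labelled Mock 60 min the correlation was 0.98 with untouched leaves and 0.47 with its own label. For the one labelled Mock 300 min it was 0.98 with untouched leaves and -0.91 with its own label. The library labelled flg22 0 min correlated at 0.98 with Mock 300 min leaves and at -0.88 with untouched leaves. Of the remaining 20 untouched and Mock libraries, 18 were nearest to their own class on clock genes and 20 on all genes. All labels were kept as deposited, and counts are also given without these 4 libraries, an alternative chosen after the data were seen.

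**Figure D1:**
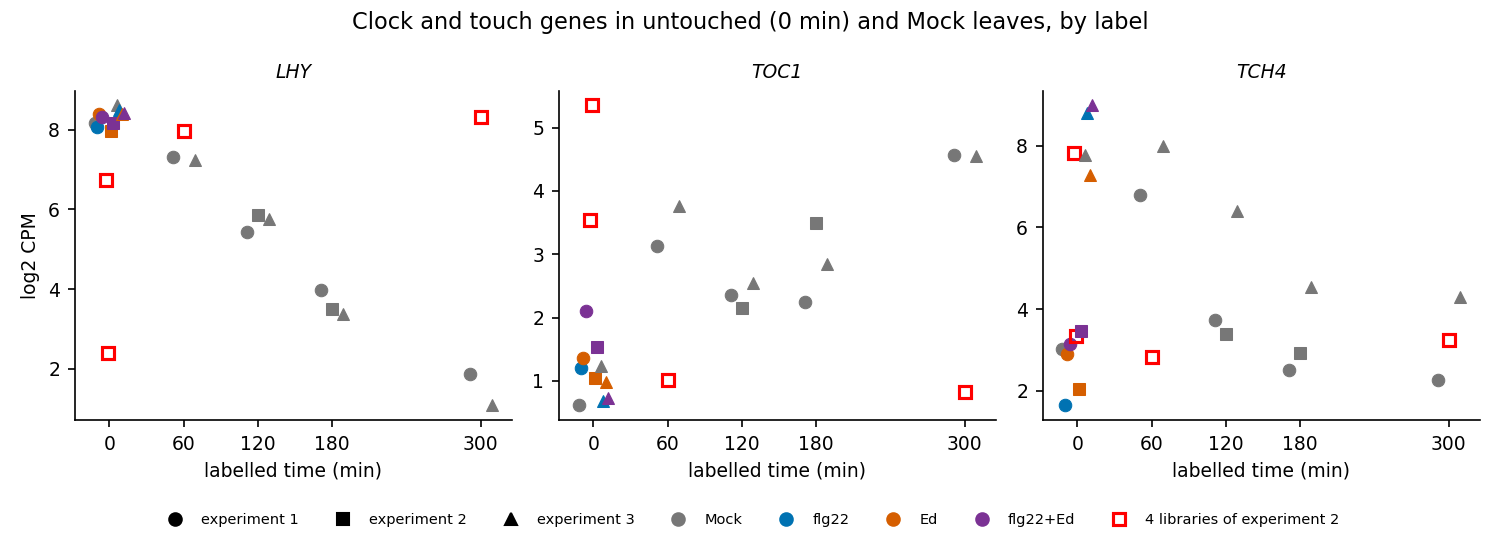
Levels of the clock genes LHY and TOC1 and of the touch gene TCH4 (log2 CPM) against the labelled time in untouched and Mock libraries, with each point 1 library and the 4 libraries of experiment 2 that stood apart as open squares. LHY in the library labelled Mock 300 min of experiment 2 lies at 316 CPM, against 3.07 CPM in experiment 1.

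Transcripts of the mutated genes were counted in these leaves, from 4.49 to 45.2 CPM for AOS, from 4.87 to 23.5 CPM for EIN2, from 0.258 to 288 CPM for PAD4 and from 0 to 4.11 CPM for ICS1. A 3′ tag outside the mutated part of a gene checks nothing about the mutation. PR1, a marker of salicylic acid signalling, had 2 counts in all, with 58 libraries at 0, which allows up to 3 counts in each, or 0.642 to 2.06 CPM. PR1 and ICS1 were too low to be tested.

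The comparison of flg22 with Mock leaves addressed the response to the flagellin peptide alone, which the design text assigns to pattern-triggered immunity (PTI). FRK1 (AT2G19190), a receptor kinase gene used as a marker of that response, had 3 counts in flg22 leaves and 1 in Mock leaves at 60 min (adjusted p = 0.694). It rose to 30.8 ± 18.6 CPM at 120 min against 0.696 ± 1.21 CPM in Mock leaves, by 6.11 ± 0.76 on the log2 scale (adjusted p = 2.53e-07). It reached 166 ± 27.4 CPM at 180 min and 272 ± 71.6 CPM at 300 min, a ratio of 1350 with an interval of 373 to 11200. WRKY33 (AT2G38470), a transcription factor gene of camalexin control, rose by 4.55 ± 0.93 at 120 min, by 5.02 ± 0.98 at 180 min and by 3.4 ± 0.92 at 300 min (adjusted p = 0.00073, 0.000141 and 0.00278). RIN4 rose by 1.25 ± 0.27, 1.39 ± 0.27 and 2.11 ± 0.28 at these times (adjusted p = 0.0015, 0.000127 and 7.43e-08). AOS fell at 300 min, with a log2 fold change of -1.7 ± 0.52 (adjusted p = 0.00748). PAD4 passed at no time, and FMO1 (AT1G19250), a synthesis gene of N-hydroxypipecolic acid, had at most 1 count in flg22 leaves at each time. PAD3 (AT3G26830), the last camalexin synthesis gene, had 11 counts against 0 at 300 min (adjusted p = 0.0923). In all, 1081 genes rose and 569 fell at 60 min, 1246 and 470 at 120 min, 2354 and 1369 at 180 min, and 3221 and 3502 at 300 min. Without the 4 libraries that stood apart, the counts were 634 and 196 at 60 min, 1802 and 977 at 120 min, 4838 genes at 180 min and 6761 at 300 min.

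EDS1 (AT3G48090), the signalling partner of PAD4, rose by 2.12 ± 0.56 at 60 min, 2.46 ± 0.57 at 120 min, 2.45 ± 0.57 at 180 min and 1.49 ± 0.56 at 300 min (adjusted p = 0.0104, 0.00312, 0.00115 and 0.0293). Without Mock replicate 2 its adjusted p was 0.13 at 60 min, and at 300 min it was 0.109 without Mock replicate 2 and 0.0546, 0.0503, 0.0671 and 0.0873 without Mock replicates 1 and 3 and flg22 replicates 1 and 2. RPS2 rose at 120 min (2.39 ± 0.7, adjusted p = 0.02) and at 300 min (2.18 ± 0.72, adjusted p = 0.013), with adjusted p = 0.165 and 0.0639 without Mock replicate 1 and 0.177 and 0.0601 without flg22 replicate 1. The count at 60 min was 402 without Mock replicate 2, 946 without flg22 replicate 1 and 762 without flg22 replicate 3. At 120 min it was 632, 645, 911 and 1111 without Mock replicates 1 and 2 and flg22 replicates 1 and 2. At 180 min it was 2285 without Mock replicate 1 and 2315 without flg22 replicate 2. Scaling by library sizes alone shifted the median of all genes by -0.116 at 60 min and 0.15 at 300 min. That scaling gave 901 rises and 873 falls at 60 min and 3841 and 2753 at 300 min.

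The largest rises after flg22 at 60 min were those of the indole glucosinolate methyltransferase gene IGMT3 (AT1G21110), at 9.82 ± 9.1 CPM against 0 counts in Mock leaves (at least 20-fold, adjusted p = 0.00251), of AT5G48430 by 6.8 ± 0.92 (adjusted p = 7.23e-06), and of the exocyst subunit gene EXO70H1 (AT3G55150), at 24.8 ± 4.37 CPM with a ratio of 94 (25.7 to 782). At 120 min AT2G36690, an oxoglutarate-dependent oxygenase gene, rose at least 70.5-fold, the wall-associated kinase-like gene WAKL4 (AT1G16150) at least 66.6-fold and AT2G31335 at least 55.4-fold. AT2G36690 rose at least 730-fold at 180 min, to 219 ± 92.7 CPM, AT5G48430 by a ratio of 2830 (508 to 112000), and AT4G25845 at least 256-fold. At 300 min EXO70H2 (AT2G39380) rose at least 819-fold, to 251 ± 56.3 CPM, AT2G36690 by a ratio of 4960 (890 to 196000), and the ethylene synthesis gene ACS7 (AT4G26200) at least 369-fold. EXO70H1 and EXO70H2, and IGMT2 (AT1G21120) and IGMT3, are close copies that 3′ tags may not separate. The largest falls were those of AT5G47610 (-4.58 ± 1.1, adjusted p = 0.00514), TINY2 (AT5G11590, ratio 0.0448, interval 0.009 to 0.137) and AT1G54120 (ratio 0.0568, 0.0113 to 0.175) at 60 min. At 120 min they were those of AT2G18890 (-2.61 ± 0.54), the raffinose synthase family gene SIP2 (AT3G57520, -2.26 ± 0.3, adjusted p = 8.88e-07) and AT4G00750 (-2.17 ± 0.45). At 180 min AT3G15720 (-3.46 ± 0.81), the gibberellin synthesis gene GA20OX3 (AT5G07200, -2.74 ± 0.64) and AT4G25433 (-2.49 ± 0.7) fell most. At 300 min the largest falls were those of AT2G27420 (-5.63 ± 1.33), ASG4 (AT1G01520, ratio 0.0287, 0.0058 to 0.087) and the starch synthase gene GBSS1 (AT1G32900, -4.91 ± 0.91). Without Mock replicate 2 of the same time, the adjusted p was 0.985 for AT5G47610, 0.417 for TINY2, 0.82 for AT1G54120, 0.377 for AT2G27420, 0.422 for ASG4 and 0.137 for GBSS1. For AT1G54120 it was also 0.0599 and 0.0535 without flg22 replicates 1 and 3, and for AT4G25433 0.0574 without flg22 replicate 2. With the 4 libraries left out AT2G27420 and GBSS1 passed at -1.94 and -1.37 (adjusted p = 0.0486 and 0.00399), and AT5G47610, TINY2, AT1G54120 and ASG4 did not. LHY at 300 min had a log2 fold change of -5.23 ± 1.03 (adjusted p = 7.45e-05, lower in 2 of 3 experiments), and 0.21 without Mock replicate 2 (adjusted p = 0.892).

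**Figure D2:**
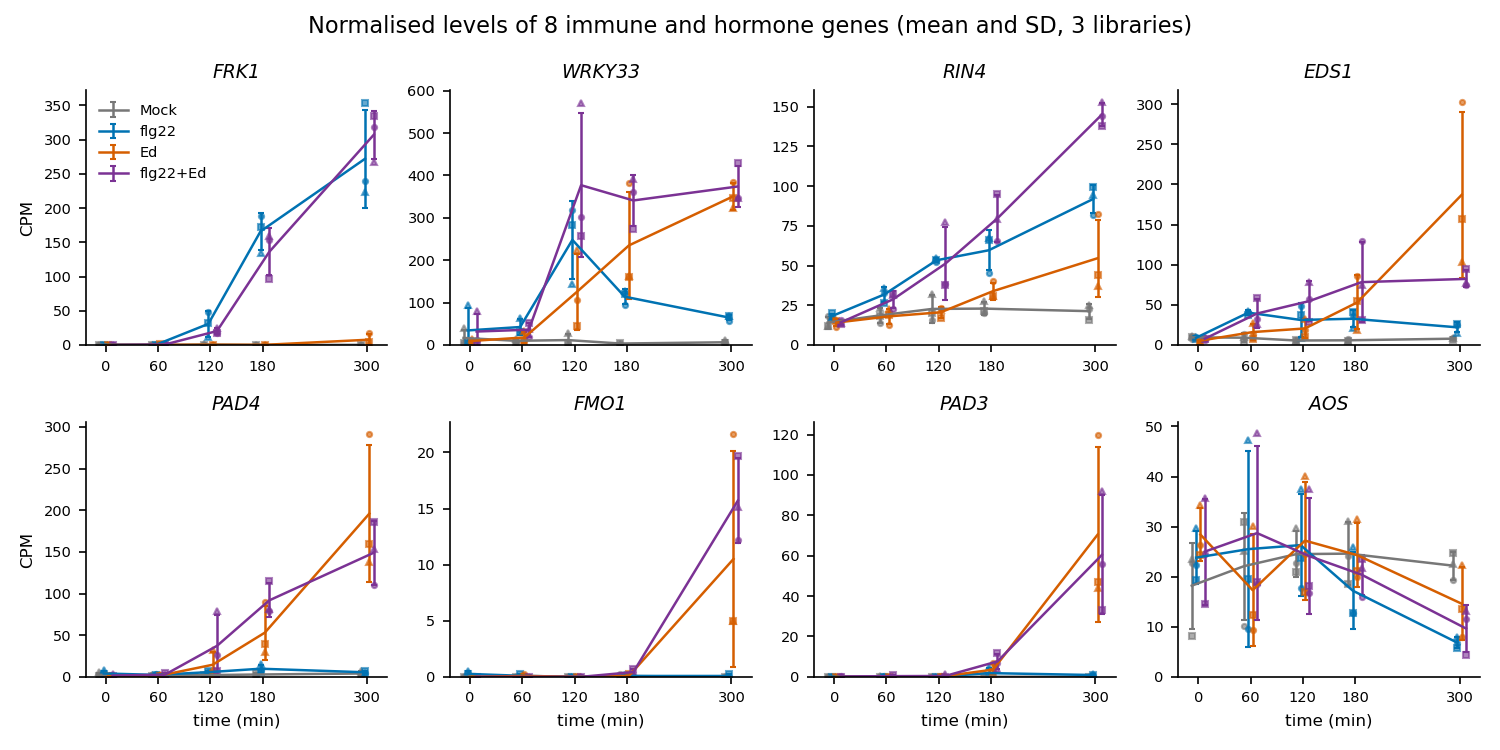
Mean CPM with SD (error bars, n = 3) and single libraries (points) of FRK1, WRKY33, RIN4, EDS1, PAD4, FMO1, PAD3 and AOS against minutes after infiltration for the 4 treatments. FRK1 reached 272 CPM with flg22 and 7.77 CPM with Ed at 300 min, while PAD4 reached 196 CPM with Ed and 5.47 CPM with flg22.

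Defence gene groups rose together after flg22. Of 19 tested early pattern-response genes, 8, 14, 17 and 17 rose at 60, 120, 180 and 300 min (10, 18, 17 and 17 adjusted over the list alone), with 4 at 60 min without the 4 libraries. Their median at 180 min was 5.65 (5.02 with members at their bound, camera adjusted p = 1.83e-16, adjusted p = 0.0868 with an estimated correlation). CYP81F2 (AT5G57220), a cytochrome P450 gene of indole glucosinolate modification, rose by 5.77 ± 0.81 at 180 min (adjusted p = 4.17e-07), WRKY29 (AT4G23550) by 7.99 ± 0.82 (adjusted p = 8.05e-10) and the peroxidase gene PER4 (AT1G14540) by 7.61 ± 0.99. Among 17 pattern receptors and signalling partners, 12, 12, 14 and 12 rose (16, 15, 17 and 12 adjusted over the list alone), with a median of 2.42 at 180 min (adjusted p = 2.82e-10, adjusted p = 0.139 with an estimated correlation). The chitin receptor gene CERK1 (AT3G21630) rose by 2.07 ± 0.4 already at 60 min (adjusted p = 0.00059), and the co-receptor gene BAK1 (AT4G33430) by 3.08 ± 0.43 and the kinase gene BIK1 (AT2G39660) by 4.26 ± 0.72 at 300 min. Of 24 WRKY genes, 9, 13, 18 and 18 rose (13, 14, 19 and 18 adjusted over the list alone), with a median of 3.94 at 180 min (adjusted p = 5.79e-14, adjusted p = 0.131 with an estimated correlation), among them WRKY30 (AT5G24110) by 6.31 ± 0.93 at 60 min and WRKY60 (AT2G25000) by 5.97 ± 0.54 at 300 min (adjusted p = 1.21e-11). Of 20 NLR receptor and effector-triggered immunity genes, 4, 8, 9 and 12 rose (7, 9, 10 and 12 adjusted over the list alone, 1 at 60 min without the 4 libraries), with a median of 1.36 at 300 min (adjusted p = 0.00111, adjusted p = 0.355 with an estimated correlation). RPM1 (AT3G07040) rose by 2.8 ± 0.69 and NDR1 (AT3G20600) by 1.89 ± 0.52.

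Protein folding and secondary metabolism genes also rose. All 14 endoplasmic reticulum chaperone genes rose at 180 and 300 min, after 1 at 60 min and 9 at 120 min (12 adjusted over the list alone), and their median of 2.97 at 180 min (adjusted p = 1.28e-21) also passed with an estimated correlation (adjusted p = 0.0399). BIP2 (AT5G42020), an HSP70 of the endoplasmic reticulum, rose by 4.31 ± 0.56 and its partner gene ERDJ3A (AT3G08970) by 4.51 ± 0.48 at 180 min (adjusted p = 1.27e-07 and 1.49e-09). Of 11 heat shock protein genes, 2, 7, 10 and 2 rose at the 4 times (9 and 11 adjusted over the list alone at 120 and 180 min), with a median of 3.49 at 180 min (adjusted p = 8.12e-08, adjusted p = 0.139 with an estimated correlation). HSP90.1 (AT5G52640) rose by 5.17 ± 0.82 and HSP101 (AT1G74310) by 3.33 ± 0.66. Of 15 phenylpropanoid and lignin genes, 7, 6, 12 and 14 rose (13 and 14 adjusted over the list alone at 180 and 300 min), with a median of 1.83 at 300 min (adjusted p = 6.44e-11, adjusted p = 0.131 with an estimated correlation). PAL1 (AT2G37040), the entry enzyme of the pathway, rose by 4.37 ± 0.51 and the lignin methyltransferase gene OMT1 (AT5G54160) by 3.7 ± 0.24 at 300 min (adjusted p = 7.25e-09 and 8.31e-16). Of 22 camalexin, tryptophan and indole glucosinolate genes, 5, 9, 13 and 14 rose and 1 fell at 60 and at 300 min (15 and 1 adjusted over the list alone at 300 min), with a median of 1.82 at 300 min (adjusted p = 4.19e-06, adjusted p = 0.139 with an estimated correlation). The myrosinase gene PEN2 (AT2G44490) rose by 2.85 ± 0.49 and CYP71A12 (AT2G30750) by 7.67 ± 1.04 at 300 min.

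Photosynthesis genes fell late in flg22 leaves. Of 36 tested, 0, 2, 15 and 35 fell at 60, 120, 180 and 300 min (29 and 36 adjusted over the list alone at the last times), with a median of -1.17 at 300 min (adjusted p = 6.22e-18, adjusted p = 0.139 with an estimated correlation). The Calvin cycle genes PRK (AT1G32060) and RCA (AT2G39730) fell with log2 fold changes of -1.84 ± 0.28 and -1.76 ± 0.28 (adjusted p = 1.07e-06 and 2.22e-06), and PSAF (AT1G31330), the member that did not pass, stood at -0.72 ± 0.33 (adjusted p = 0.076). Of 14 salicylic acid genes, 3, 3, 4 and 8 rose (8 adjusted over the list alone at 300 min), with a median of 1.57 at 300 min (adjusted p = 0.0213, adjusted p = 0.47 with an estimated correlation, adjusted p = 0.0802 without the 4 libraries). The regulator gene CBP60G (AT5G26920) rose by 5.77 ± 1.04 at 300 min, while SARD1 (AT1G73805) stood at 1.05 ± 0.95 (adjusted p = 0.401). Of 15 ethylene genes, 8 rose at 300 min (8 adjusted over the list alone, median 1.06, adjusted p = 0.00243, adjusted p = 0.245 with an estimated correlation). ACS2 (AT1G01480) rose by 4.94 ± 0.83. At 300 min the other lists did not pass. Of 22 jasmonate genes 4 rose and 2 fell (adjusted p = 0.618). Of 4 N-hydroxypipecolic acid genes 2 rose (adjusted p = 0.0852), of 23 abscisic acid genes 3 rose and 12 fell (0.0902). Of 17 auxin genes 3 rose and 8 fell (0.0695). IAA3 (AT1G04240) stood at -2.41 ± 0.35. Of 20 clock genes 2 rose and 8 fell (0.513), but 2 and 1 without the 4 libraries. Of 13 ribosomal protein genes 0 passed (0.329), but 9 rose without the 4 libraries. Among cell type markers, 1 of 7 guard cell genes rose (0.652), 1 of 6 epidermis genes fell (0.557), namely the wax gene CER1 (AT1G02205) at -2.44 ± 0.47, and 1 of 8 phloem genes fell (0.444).

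**Figure D3:**
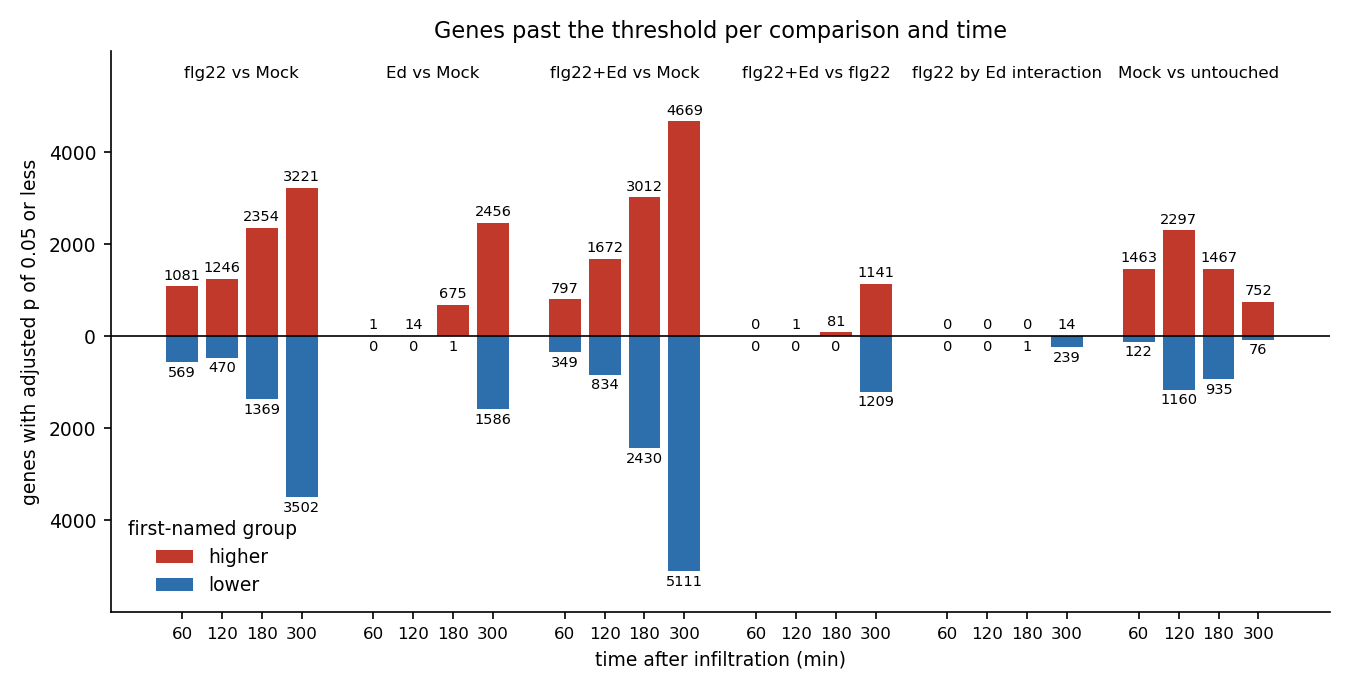
Number of genes that rose (above 0) or fell (below 0) at an adjusted p of 0.05 in each comparison and time, all 60 libraries in 1 fit. The largest bars are those of flg22+Ed against Mock at 300 min, with 4669 rises and 5111 falls.

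The comparison of Ed with Mock leaves addressed the response to induced AvrRpt2, which the design text assigns to effector-triggered immunity (ETI). At 60 min 1 gene rose, AT3G13310, a DnaJ domain gene, at 107 ± 45.3 against 16.9 ± 3.8 CPM (2.66 ± 0.45, adjusted p = 0.00701), and at 120 min 14 genes rose and 0 fell. At 180 min 675 rose and 1 fell, and at 300 min 2456 rose and 1586 fell. PAD4 rose by 4.19 ± 0.71 at 180 min and by 5.72 ± 0.73 at 300 min, to 196 ± 82.6 against 4 ± 2.9 CPM (adjusted p = 9.71e-05 and 1.09e-07), and EDS1 by 3.14 ± 0.57 and 4.58 ± 0.59 (adjusted p = 0.000239 and 1.26e-07). WRKY33 rose by 6.06 ± 1.02 at 180 min and 5.84 ± 1 at 300 min (adjusted p = 8.64e-05 and 1.63e-05), RIN4 by 1.36 ± 0.27 (adjusted p = 0.000177) and RPS2 by 2.98 ± 0.71 (adjusted p = 0.00131) at 300 min. PAD3 reached 70.4 ± 43.4 CPM at 300 min against 0 counts (at least 211-fold, adjusted p = 1.1e-07) and FMO1 10.5 ± 9.62 CPM (at least 31.4-fold, adjusted p = 6.06e-06). FRK1 reached 7.77 ± 7.95 CPM at 300 min, a ratio of 35.1 (9.41 to 294, adjusted p = 6.91e-05). Without the 4 libraries the counts were 1, 21, 868 and 3669.

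The largest Ed responses at 120 min were those of the acylhydrolase gene DLAH (AT1G30370, ratio 124, interval 22 to 4950, adjusted p = 0.0314), the lectin-like gene PP2-B13 (AT1G56240, 70.2, 19.1 to 584, adjusted p = 0.0277) and AT5G52760 (5.09 ± 1.1, adjusted p = 0.0467). Also called were SARD1, a regulator of salicylic acid synthesis (4.7 ± 1.01, adjusted p = 0.0467), and ERF6 (AT4G17490, 4.48 ± 0.91, adjusted p = 0.0314). At 180 min AT5G22520 rose most, by a ratio of 1200 (215 to 47500), with AT3G28580 at least 99.2-fold and the metacaspase gene MC8 (AT1G16420) at least 56.4-fold. The single fall was that of the cutin synthesis gene GPAT4 (AT1G01610, -0.95 ± 0.24, adjusted p = 0.0116). PAD3 had a ratio of 37.6 at 180 min (6.37 to 1520, adjusted p = 0.0254). At 300 min the natriuretic peptide gene PNP-A (AT2G18660) rose at least 232-fold and the methionine sulfoxide reductase gene MSRB9 (AT4G21850) at least 207-fold. AT2G27420 (ratio 0.00873, 0.00179 to 0.0258), BBX31 (AT3G21890, ratio 0.0174, 0.00208 to 0.0646) and COL2 (AT3G02380, -4.84 ± 0.96) fell most. Without Mock replicate 2 of 300 min, the adjusted p was 0.333 for AT2G27420, 0.636 for BBX31 and 0.179 for COL2. LHY stood at -4.88 ± 1.01 at 300 min (adjusted p = 0.000275, lower in 1 of 3 experiments) and at 0.56 without that library (adjusted p = 0.754).

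Single libraries decided the early Ed calls. AT3G13310 had an adjusted p of 0.0545, 0.32, 0.0611 and 0.264 without Mock replicates 1, 2 and 3 and Ed replicate 3, and the count at 60 min was 0 without Mock replicate 2, Mock replicate 3 or Ed replicate 3. At 120 min the count was 0 without Mock replicate 1, Mock replicate 2 or Ed replicate 3, 9 and 56 without Ed replicates 1 and 2, 35 without Mock replicate 3, and 40 with a replicate block. Without Mock replicate 1, Mock replicate 2 and Ed replicate 3 the adjusted p was 0.477, 0.864 and 0.815 for DLAH, 0.399, 0.864 and 0.47 for PP2-B13, 0.756, 0.864 and 0.68 for ERF6, 0.953, 1 and 0.73 for AT5G52760 and 0.953, 1 and 1 for SARD1. AT5G52760 also had 0.0764 without Ed replicate 1. At 180 min the count was 372 and 422 without Mock replicates 1 and 2 and 316 without Ed replicate 1. At 300 min it was 2125 without Ed replicate 1 and 2609 without Mock replicate 2. GPAT4 had an adjusted p of 0.187, 0.0635, 0.0555 and 0.168 without Ed replicates 1 and 3 and Mock replicates 2 and 3. PAD3 at 180 min had 0.182, 0.109, 0.0691 and 0.276 without Mock replicates 1, 2 and 3 and Ed replicate 1.

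The salicylic acid genes rose as a group after Ed. Of 14 tested, 0, 1, 6 and 13 rose at 60, 120, 180 and 300 min (4, 9 and 13 adjusted over the list alone from 120 min on), with a median of 5.17 at 300 min (adjusted p = 9.18e-11, adjusted p = 0.0649 with an estimated correlation). The salicylic acid synthesis gene PBS3 (AT5G13320) rose by 7.23 ± 0.77 and the transporter gene EDS5 (AT4G39030) by 6.57 ± 0.82 at 300 min (adjusted p = 4.77e-09 and 7.61e-08). SARD1 rose by 6.09 ± 0.91, and EPS1 (AT5G67160) stood at -0.99 ± 0.63 (adjusted p = 0.268). All 4 N-hydroxypipecolic acid genes rose at 300 min (4 adjusted over the list alone, median 6.88, or 5.06 with members at their bound, adjusted p = 6.97e-05, adjusted p = 0.0654 with an estimated correlation), with ALD1 (AT2G13810) up at least 35.3-fold and SARD4 (AT5G52810) by 4.26 ± 0.42. Of 22 camalexin, tryptophan and indole glucosinolate genes, 8 rose at 180 min (13 and 1 fall adjusted over the list alone, median 1.74), where the list passed with both correlations (adjusted p = 2.34e-17, adjusted p = 0.0114 with an estimated correlation), and 18 rose and 1 fell at 300 min. That 1 was the indole glucosinolate regulator gene MYB34 (AT5G60890, -2.37 ± 0.4). Of 19 early pattern-response genes, 1, 14 and 17 rose at 120, 180 and 300 min (8, 15 and 17 adjusted over the list alone). They had a median of 5.17 at 180 min (4.35 with members at their bound) that passed with both correlations (adjusted p = 2.82e-27, adjusted p = 0.0114 with an estimated correlation). The kinase genes MPK11 (AT1G01560) and MKK4 (AT1G51660) rose by 8.25 ± 0.95 and 4.47 ± 0.66 at 300 min (adjusted p = 1.95e-08 and 1.45e-06).

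Of 17 pattern receptors, 7 and 14 rose at 180 and 300 min (15 and 16 adjusted over the list alone, median 2.42 at 300 min, adjusted p = 2.74e-13, adjusted p = 0.0712 with an estimated correlation). The oxidase gene RBOHD (AT5G47910) rose by 3.58 ± 0.56. Of 20 NLR and effector-triggered immunity genes, 6 and 16 rose (11 and 17 adjusted over the list alone, median 2.11 at 300 min, adjusted p = 1.82e-11, adjusted p = 0.0649 with an estimated correlation). SAG101 (AT5G14930) rose by 3.18 ± 0.55 and NDR1 by 3.33 ± 0.52. Of 24 WRKY genes, 8 and 18 rose (11 and 20 adjusted over the list alone, median 3.53, or 3.5 with members at their bound, at 300 min, adjusted p = 2.8e-13, adjusted p = 0.0712 with an estimated correlation). WRKY46 (AT2G46400) rose by 6.96 ± 1.01, while WRKY22 (AT4G01250) stood at 1.18 ± 0.95 (adjusted p = 0.398). At 300 min all 14 endoplasmic reticulum chaperone genes rose (14 adjusted over the list alone, 11 without the 4 libraries, median 2.05, adjusted p = 5.46e-11, adjusted p = 0.0712 with an estimated correlation), BIP3 (AT1G09080) by 6.4 ± 0.96 among them. Of 11 heat shock genes, 8 rose (8 adjusted over the list alone, median 2.9, adjusted p = 3.44e-05, adjusted p = 0.201 with an estimated correlation). Of 10 mitochondrial stress genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 2.25, adjusted p = 0.000467, adjusted p = 0.0712 with an estimated correlation). OM66 (AT3G50930) rose by 7.32 ± 1.09. Of 15 ethylene genes, 7 rose (8 adjusted over the list alone, median 1.4, adjusted p = 0.00118, adjusted p = 0.195 with an estimated correlation). Of 10 touch genes 5 rose (6 adjusted over the list alone, median 2.88, adjusted p = 0.00328, adjusted p = 0.253 with an estimated correlation).

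Photosynthesis genes fell after Ed in 12 of 36 cases at 300 min (13 adjusted over the list alone, median -0.43, adjusted p = 5.76e-06, adjusted p = 0.494 with an estimated correlation). PRK stood at -1.09 ± 0.27 (adjusted p = 0.00213). Of 15 phenylpropanoid genes 3 rose and 1 fell at 300 min (5 and 1 adjusted over the list alone, adjusted p = 0.114), 7 and 1 without the 4 libraries. C4H (AT2G30490) stood at 1.19 ± 0.46 (adjusted p = 0.0516) and OMT1 at 0.4 ± 0.21 (adjusted p = 0.179). Of 6 epidermis genes 4 fell at 300 min (4 adjusted over the list alone, median -0.82, adjusted p = 0.00874, adjusted p = 0.11 with an estimated correlation). Outside that list, the sucrose exporter gene SWEET11 (AT3G48740), a phloem gene, stood at -1.48 ± 0.24. Jasmonate genes rose in 5 and fell in 2 of 22 cases (adjusted p = 0.342), auxin genes in 3 and 6 of 17 (0.138), 2 and 3 without the 4 libraries, and cell death genes rose in 3 of 7 (0.0491, adjusted p = 0.193 with an estimated correlation, 0.0523 with a replicate block). Abscisic acid genes fell in 4 of 23 cases (0.525) and clock genes in 6 of 20 (0.285), or 2 and 1, with 1 rise in each, without the 4 libraries.

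The comparison of leaves given both elicitors with Mock leaves addressed the joint response. At 60 min 797 genes rose and 349 fell, at 120 min 1672 and 834, at 180 min 3012 and 2430, and at 300 min 4669 and 5111. FRK1 reached 307 ± 35.1 CPM at 300 min (ratio 1420, 393 to 11700), PAD4 149 ± 38.2 CPM (5.33 ± 0.72, adjusted p = 3.71e-08), PAD3 60.4 ± 29.5 CPM (at least 196-fold, adjusted p = 1.7e-08) and FMO1 15.7 ± 3.81 CPM (at least 46.9-fold, adjusted p = 1.92e-07). PAD4 and EDS1 had already risen at 120 min, by 4.13 ± 0.74 and 3.26 ± 0.58 (adjusted p = 0.000106 and 8.98e-05). At that time EDS1 also passed with flg22 alone (2.46 ± 0.57, adjusted p = 0.00312), neither passed with Ed alone (adjusted p = 0.178 and 0.366), and neither differed past the threshold from flg22 alone (adjusted p = 0.245 and 1). WRKY33 rose by 5.93 ± 1 and RIN4 by 2.77 ± 0.28 at 300 min (adjusted p = 2.29e-06 and 5.6e-11). The largest rises at 60 min were those of IGMT3 (at least 26.3-fold), WRKY30 (6.48 ± 0.93, adjusted p = 2.21e-05) and AT5G48430 (6.4 ± 0.91). At 120 min they were those of AT2G04515 (at least 189-fold), AT2G31335 (at least 73.7-fold) and DLAH (ratio 748, 134 to 29600). At 180 min AT2G36690 (at least 590-fold), AT1G51920 (at least 270-fold) and the Pep3 precursor gene PROPEP3 (AT5G64905, at least 263-fold, to 87.1 ± 36.9 CPM) rose most. At 300 min the largest were EXO70H2 (at least 1060-fold), AT1G51920 (at least 526-fold) and AT2G36690 (ratio 5590, 1000 to 221000). With the 4 libraries left out, 496, 3800, 6579 and 9978 genes passed at the 4 times.

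The largest falls with both elicitors at 60 min were those of AT1G19490, CYCP2;1 (AT3G21870) and MES10 (AT3G50440, -3.22 ± 0.88, -3.2 ± 0.86 and -2.96 ± 0.75, adjusted p = 0.0195, 0.0162 and 0.0114), which had adjusted p = 0.663, 0.869 and 0.849 without Mock replicate 2. Without single flg22+Ed libraries their adjusted p lay between 0.0505 and 0.0934 for AT1G19490 (replicates 1 and 3), CYCP2;1 (replicates 1, 2 and 3) and MES10 (replicates 1 and 2). At 120 min AT4G25780 (-2.32 ± 0.48), the coronatine-induced gene CORI3 (AT4G23600, -2.25 ± 0.57) and AT5G20110 (-2.23 ± 0.54) fell most. At 180 min the largest were those of GA20OX3 (-3.55 ± 0.75), AT3G15720 (-3.42 ± 0.84) and AT4G25433 (-3.16 ± 0.8). At 300 min AT3G06880 was at least 25.6-fold lower (adjusted p = 0.00014), AT2G27420 fell by 6.15 ± 1.45 and ASG4 had a ratio of 0.0109 (0.000273 to 0.0626), and without Mock replicate 2 the last 2 had adjusted p = 0.251 and 0.24. The count at 60 min was 210 and 1788 without Mock replicates 2 and 3, and 544 and 684 without flg22+Ed replicates 2 and 3. At 120 min it was 1191 and 1206 without Mock replicates 1 and 2 and 886 without flg22+Ed replicate 3. Scaling by library sizes alone shifted the median of all genes by -0.119 at 60 min and gave 693 rises and 621 falls there.

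At 300 min many listed genes had risen with both elicitors. All 24 WRKY genes rose (24 adjusted over the list alone, median 5.55, or 5.28 with members at their bound, adjusted p = 2.71e-09, adjusted p = 0.141 with an estimated correlation). WRKY60 rose by 6.01 ± 0.54 (adjusted p = 4.15e-12). Of 19 early pattern-response genes, 6, 17, 18 and 17 rose at the 4 times (17 adjusted over the list alone at 300 min, median 6.65, or 6.16 with members at their bound, adjusted p = 6.02e-09, adjusted p = 0.128 with an estimated correlation). Of 14 salicylic acid genes, 1, 8, 8 and 13 rose (13 and 1 fall adjusted over the list alone at 300 min, median 4.96, adjusted p = 0.000154, adjusted p = 0.206 with an estimated correlation), PBS3 by 8.03 ± 0.8 (adjusted p = 3.13e-11) and NPR1 (AT1G64280) by 2.04 ± 0.34. Of 22 camalexin, tryptophan and indole glucosinolate genes, 21 rose and 1 fell (median 3.78, adjusted p = 1.32e-09, adjusted p = 0.0934 with an estimated correlation), with the tryptophan synthesis genes TSA1 (AT3G54640) and ASA1 (AT5G05730) up by 3.98 ± 0.3 and 2.91 ± 0.24 (adjusted p = 1.08e-13 and 6.67e-13). Heat shock genes rose in 11 of 11 cases from 120 min on (median 3.02 at 120 min, adjusted p = 1.48e-08, adjusted p = 0.104 with an estimated correlation), HSP101 by 3.2 ± 0.6 at 120 min. All 36 photosynthesis genes fell at 300 min, after 13 at 120 min and 31 at 180 min (31 and 34 adjusted over the list alone), with a median of -2.15 at 300 min (adjusted p = 1.1e-26, adjusted p = 0.104 with an estimated correlation). The Rubisco gene RBCS2B (AT5G38420) fell by 3.28 ± 0.28 and the antenna gene LHCB2.1 (AT2G05100) by 2.21 ± 0.2 (adjusted p = 1.45e-12 and 4.77e-12).

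Receptors rose in 16 of 17 cases at 300 min (median 3.42, adjusted p = 1.47e-07, adjusted p = 0.16 with an estimated correlation), NLR genes in 17 of 20 (2.14, adjusted p = 2.41e-05, adjusted p = 0.191 with an estimated correlation). Ethylene genes rose in 12 of 15 (2.41, adjusted p = 0.00297, adjusted p = 0.206 with an estimated correlation). ACS2 rose by 6.79 ± 0.77. Endoplasmic reticulum chaperone genes rose in 14 of 14 cases (3.08, adjusted p = 2.71e-09, adjusted p = 0.114 with an estimated correlation), phenylpropanoid genes in 14 of 15 (2.22, adjusted p = 4.45e-08, adjusted p = 0.128 with an estimated correlation). Mitochondrial stress genes rose in 8 of 10 with 1 fall (3.38, adjusted p = 0.0038, adjusted p = 0.128 with an estimated correlation), and N-hydroxypipecolic acid genes in 4 of 4 (7.79, or 5.87 with members at their bound, adjusted p = 0.00416, adjusted p = 0.128 with an estimated correlation). Jasmonate genes split, with 8 of 22 rising and 5 falling (adjusted p = 0.403), LOX4 (AT1G72520) by 5.31 ± 0.9 and LOX2 (AT3G45140) at -2.12 ± 0.46 (adjusted p = 2.51e-06 and 0.00012).

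**Figure D4:**
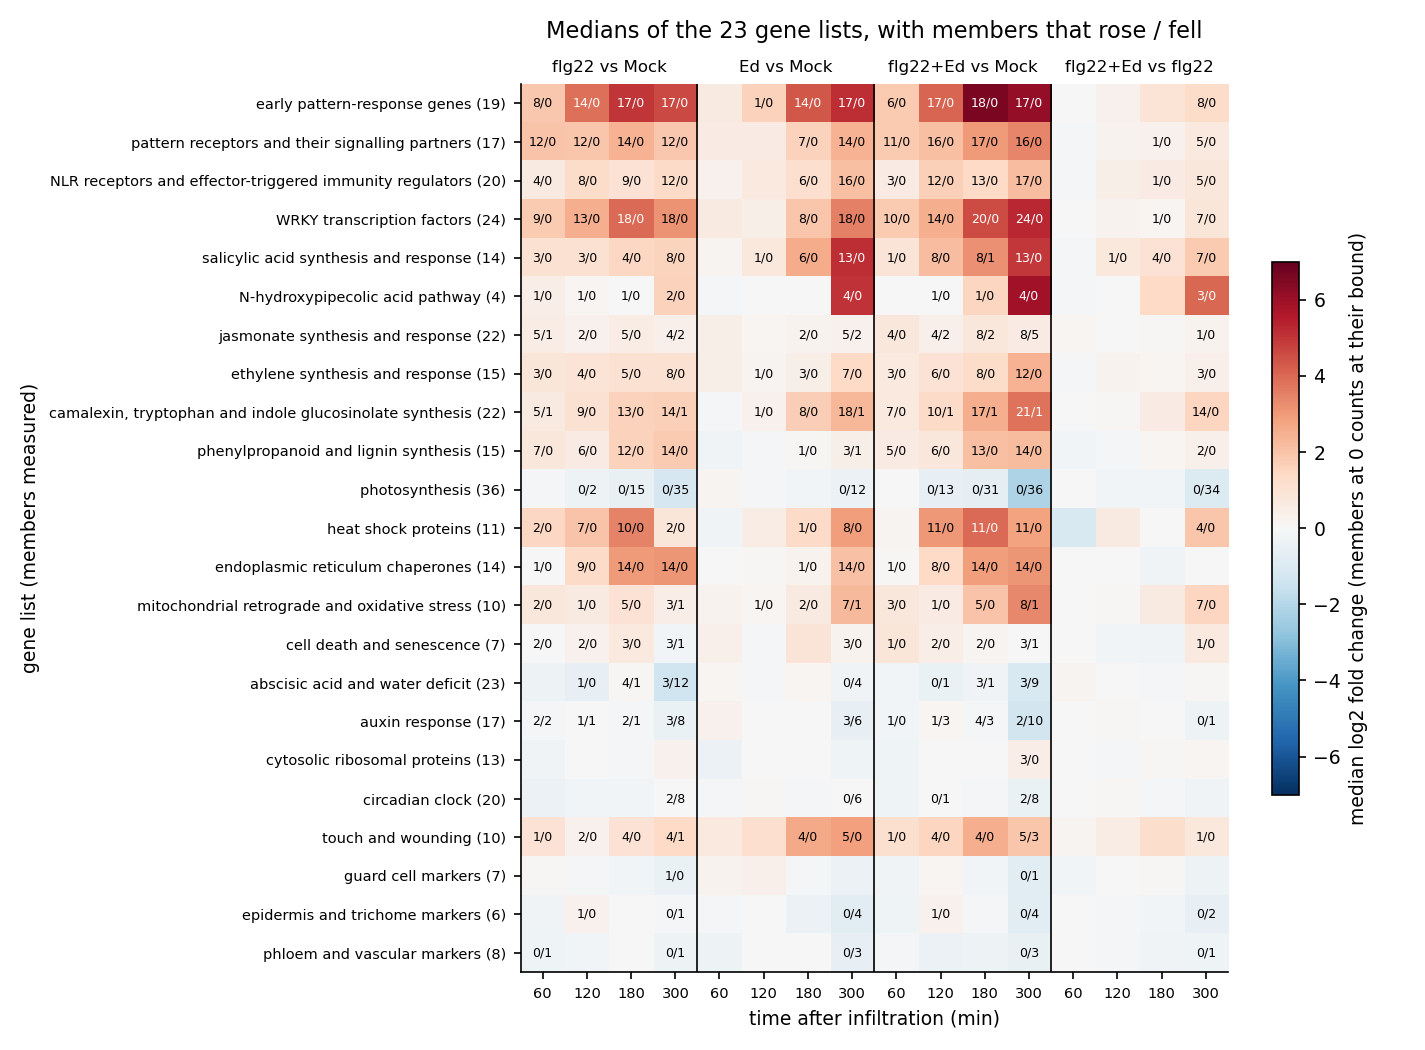
Median log2 fold change of each of the 23 gene lists, members at their bound where a group had 0 counts (colour), and the numbers of members that rose and fell (text), by comparison and time. The photosynthesis list has a median of -2.15 with both elicitors at 300 min and the WRKY list one of 5.28.

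The comparison of leaves given both elicitors with leaves given flg22 addressed what Ed added in the presence of flg22. At 60 min 0 genes passed in edgeR, limma-voom and DESeq2 (193 at an unadjusted p of 0.05), at 120 min 1 rose, at 180 min 81 rose and 0 fell, and at 300 min 1141 rose and 1209 fell. The gene at 120 min was PBS3 (4.75 ± 0.86, adjusted p = 0.0262, 22 ± 24.7 against 0.859 ± 0.655 CPM), whose call ended without any of flg22 replicates 1, 2 and 3 or flg22+Ed replicate 3 (adjusted p = 0.756, 0.503, 0.156 and 1). PBS3 rose by 5.32 ± 0.72 at 180 min and 5.42 ± 0.68 at 300 min (adjusted p = 4.54e-05 and 4.75e-07). PAD4 rose by 4.76 ± 0.67 (adjusted p = 3.31e-06), PAD3 by 6.06 ± 0.77 (adjusted p = 2.69e-06, 60.4 ± 29.5 against 0.895 ± 0.453 CPM) and FMO1 by a ratio of 181 (32.1 to 7210, adjusted p = 3.74e-06) at 300 min. FRK1 stood at 0.17 ± 0.44 (adjusted p = 0.845), RIN4 at 0.66 ± 0.26 (adjusted p = 0.0789) and CYP81F2 at 0.72 ± 0.58 (adjusted p = 0.455). EDS1 rose by 1.9 ± 0.51 (adjusted p = 0.00894, 0.0515 without flg22 replicate 3). WRKY33 rose by 2.53 ± 0.82 (adjusted p = 0.031), but not past the threshold without flg22 replicates 1, 2 or 3 or flg22+Ed replicates 2 or 3 (adjusted p = 0.144, 0.0763, 0.077, 0.0676 and 0.0622).

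The largest rises at 180 min were those of BAP2 (AT2G45760), a suppressor of cell death (at least 88.5-fold, adjusted p = 0.000226), AT5G52730 (at least 20-fold) and AT1G13310 (at least 16.7-fold), and at 300 min those of AT1G55775 (at least 46.4-fold), the ubiquitin ligase gene ARI12 (AT1G05880, ratio 399, 71.2 to 15800) and NAC061 (AT3G44350, at least 41.4-fold). The germin gene GER3 (AT5G20630, -4 ± 1.1, adjusted p = 0.00987), AT3G16670 (-2.96 ± 1, adjusted p = 0.0387) and AT4G18970 (-2.53 ± 0.65, adjusted p = 0.00606) fell most at 300 min. Without flg22 replicate 1 these last 3 had adjusted p = 0.073, 0.321 and 0.112, and without flg22+Ed replicate 3 0.0765, 0.187 and 0.0546, with 0.142 for AT3G16670 without flg22+Ed replicate 1. Without flg22 replicates 1, 2 and 3 and flg22+Ed replicate 2, AT5G52730 had adjusted p = 0.158, 0.135, 0.0687 and 0.101, and AT1G13310 0.222, 0.186, 0.0937 and 0.22. The count at 120 min was 0 without flg22 replicate 1, 2 or 3 or flg22+Ed replicate 3 and 9 without flg22+Ed replicate 2. At 180 min it was 22, 23 and 51 without flg22 replicates 1 and 2 and flg22+Ed replicate 2, and 135 with a replicate block. At 300 min it was 841 without flg22 replicate 1 and 1299 without flg22+Ed replicate 3. With the 4 libraries left out 0, 1, 108 and 3545 genes passed, 1531 of the last rising and 2014 falling.

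Of 14 salicylic acid genes tested, 1, 4 and 7 rose at 120, 180 and 300 min (3, 6 and 9 adjusted over the list alone), with a median of 1.84 at 300 min (adjusted p = 4.86e-07, adjusted p = 0.208 with an estimated correlation), EDS5 by 5.43 ± 0.75 and SARD1 by 4.41 ± 0.8 (adjusted p = 2.29e-06 and 0.000151). Of 10 mitochondrial stress genes 7 rose at 300 min (8 adjusted over the list alone, median 1.52, adjusted p = 8.82e-07), a list that also passed with an estimated correlation (adjusted p = 0.0413). CYP81D8 (AT4G37370) rose by 4.9 ± 0.6 and GSTU24 (AT1G17170) by 4.84 ± 0.77. Of 22 camalexin, tryptophan and indole glucosinolate genes 14 rose (16 and 1 fall adjusted over the list alone, median 1.51, adjusted p = 2.27e-11, adjusted p = 0.0616 with an estimated correlation). CYP71A13 (AT2G30770) rose by 6.26 ± 1.15 and PAT1 (AT5G17990) by 1.49 ± 0.19. Of 36 photosynthesis genes 34 fell (36 adjusted over the list alone, median -0.94, adjusted p = 3.85e-25, adjusted p = 0.174 with an estimated correlation). RBCS2B stood at -1.8 ± 0.27 and LHCB1.1 (AT1G29920) at -1.28 ± 0.24. N-hydroxypipecolic acid genes rose in 3 of 4 cases (4 adjusted over the list alone, median 4.02, adjusted p = 5.64e-05, adjusted p = 0.0772 with an estimated correlation). WRKY genes rose in 7 of 24 (9, median 0.84, adjusted p = 3.29e-05, adjusted p = 0.521 with an estimated correlation) and early pattern-response genes in 8 of 19 (9, median 1.28, adjusted p = 2.21e-05, adjusted p = 0.485 with an estimated correlation). MPK11 rose by 6 ± 0.81 and WRKY55 (AT2G40740) by 5.26 ± 0.68 (adjusted p = 1.53e-06 and 1.22e-06), while WRKY29 stood at -0.16 ± 0.56 (adjusted p = 0.892). Receptors rose in 5 of 17 cases (7, median 0.68, adjusted p = 4.07e-05, adjusted p = 0.504 with an estimated correlation). NLR genes rose in 5 of 20 (8, median 0.79, adjusted p = 4.07e-05, adjusted p = 0.391 with an estimated correlation) and heat shock genes in 4 of 11 (9, median 1.92, adjusted p = 8.16e-05, adjusted p = 0.391 with an estimated correlation). The heat shock list stood lower at 60 min, where none passed (2 falls adjusted over the list alone, median -1.06, adjusted p = 1.38e-10, adjusted p = 0.0772 with an estimated correlation). None of 14 endoplasmic reticulum chaperone genes passed (adjusted p = 0.838), with BIP2 at 0.26 ± 0.49. PAL1 did not pass either, at 0.48 ± 0.45 (adjusted p = 0.528) among the phenylpropanoid genes, of which 2 of 15 rose (adjusted p = 0.144).

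The interaction of flg22 and Ed addressed whether the responses added on the log2 scale, the scale of the model. At 300 min 239 genes had a negative interaction, a joint response below the sum of both single responses, and 14 a positive one. WRKY30 had an interaction of -7.37 ± 1.46 (adjusted p = 0.00354), CYP81F2 of -5.62 ± 1.04 (adjusted p = 0.00189), IGMT2 of -5.65 ± 1.12 (adjusted p = 0.00354) and SARD4 of -2.96 ± 0.53 (adjusted p = 0.00143). AT5G16170 and AT1G51920, each with a group at 0 counts, were also most negative (adjusted p = 0.00158 and 0.01, and for AT1G51920 0.0612 and 0.074 without Mock replicates 1 and 2). Of the 239 genes, 238 had risen with Ed alone and 231 with each elicitor alone. Their median levels were 2.04 CPM in Mock, 52.2 in flg22, 49 in Ed and 89.5 in flg22+Ed leaves. Of these 239, 170 (71.1%) kept a negative call without the 4 libraries. The largest positive interactions were those of the flavonoid genes TT4 (AT5G13930, 4.97 ± 1.33, adjusted p = 0.039) and F3H (AT3G51240, 3.78 ± 1.03, adjusted p = 0.0449) and of AT3G12320 (2.76 ± 0.65, adjusted p = 0.0163), and without the 4 libraries they had adjusted p = 0.288, 0.198 and 0.0275. TT4 had adjusted p between 0.065 and 0.563 without any of 9 single libraries and F3H between 0.0522 and 0.777 without any of 10, highest for both without Mock replicate 2. AT3G12320 had 0.0785, 0.549 and 0.0503 without Ed replicate 1, Mock replicate 2 and flg22 replicate 2. FRK1 had an interaction of -4.74 ± 1.06 (adjusted p = 0.011). That adjusted p was 0.145 without Ed replicate 1, 0.104 without Mock replicate 2 and 0.0523 without the 4 libraries.

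No gene passed for the interaction at 60 or 120 min in edgeR (560 and 215 at an unadjusted p of 0.05), with 0 and 0 in limma-voom and 1 and 0 in DESeq2. At 180 min IGMT2 alone passed (-6.21 ± 1.12, adjusted p = 0.0299), and the count was 31 with a replicate block and 53 without the 4 libraries. That count was 0 without most single libraries, 9 without Ed replicate 3 and 1 without flg22 replicate 1 or Ed replicate 2, and IGMT2 had adjusted p from 0.0655 to 0.566 in the 9 cases that ended its call (Mock and flg22+Ed replicates 1, 2 and 3, flg22 replicates 2 and 3 and Ed replicate 1). At 300 min the count was 100 and 72 without Mock replicates 1 and 2, 95 without Ed replicate 1, 137 without flg22 replicate 2, 126, 155 and 140 without flg22+Ed replicates 1, 2 and 3, and 0 without the whole of experiment 1 or 2. Without the 4 libraries 7 positive and 234 negative genes passed.

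Early pattern-response genes had negative interactions. At 180 min none of 19 passed over all genes and 10 passed adjusted over the list alone, with a median of -3.55 (-2.94 with members at their bound) and a camera call that held with both correlations (adjusted p = 3.43e-24, adjusted p = 0.0449 with an estimated correlation). At 300 min 4 passed (15 adjusted over the list alone, median -3.5, or -3.31 with members at their bound, adjusted p = 8.29e-14, adjusted p = 0.162 with an estimated correlation). Of 14 endoplasmic reticulum chaperone genes 8 were negative at 300 min (14 adjusted over the list alone, 5 without the 4 libraries, median -2.09, adjusted p = 1.51e-18, adjusted p = 0.0506 with an estimated correlation). CRT3 (AT1G08450) stood at -2.51 ± 0.46 (adjusted p = 0.00174) and ERDJ3A at -3.19 ± 0.64 (adjusted p = 0.00363, 0.0876 without Ed replicate 1). WRKY genes were negative in 4 of 24 cases (10 adjusted over the list alone, median -2.64, or -1.99 with members at their bound, adjusted p = 1.27e-10, adjusted p = 0.3 with an estimated correlation). WRKY6 (AT1G62300) stood at -3.84 ± 0.81 and WRKY60 at -3.36 ± 0.66. No receptor gene passed over all genes and 12 of 17 did adjusted over the list alone (median -1.88, adjusted p = 5.08e-09, adjusted p = 0.319 with an estimated correlation). Salicylic acid genes passed in 2 of 14 cases (6 adjusted over the list alone, median -1.75, adjusted p = 4.92e-05, adjusted p = 0.392 with an estimated correlation). PBS3 stood at -1.82 ± 0.88 (adjusted p = 0.423) and PAD4 at -0.97 ± 0.93 (adjusted p = 0.79). Of 22 camalexin, tryptophan and indole glucosinolate genes 4 were negative at 300 min (adjusted p = 0.054), and none of 36 photosynthesis genes passed at a median of -0.47 (adjusted p = 6.35e-06, adjusted p = 0.668 with an estimated correlation).

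Over whole gene sets chosen by their mean effect, the Ed response with flg22 was set against that without it. At 180 min the median signed effect over 775 genes was 1.1 ± 0.227 with flg22 and 2.2 ± 0.719 without it (SD over 3 experiments), a difference of -1.06 ± 0.582 that was negative in all 3 experiments. At 300 min it was 0.791 ± 0.119 against 1.01 ± 0.314 over 6023 genes, a difference of -0.242 ± 0.239 that was negative in 2 of 3. At 120 min the difference was -0.896 ± 0.772 over 62 genes (-1.41, -1.27 and -0.00789 in experiments 1, 2 and 3), and at 60 min -1.42 ± 0.356 for 1 gene. The flg22 response differed with minus without Ed by -0.48 ± 0.14, -0.0828 ± 0.561, -0.112 ± 0.232 and -0.104 ± 0.123 at the 4 times. With 3 experiments the exact two-sided sign-flip test cannot give a p below 0.25. On the linear CPM scale, as a share of the mean effect, the Ed difference was 0.182 ± 0.568 at 120 min, 0.175 ± 0.54 at 180 min and -0.299 ± 0.212 at 300 min. It was negative in 1, 1 and 3 of 3 experiments at these times.

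Genes called with both single elicitors in the same direction numbered 1 at 60 min, 12 at 120 min, 497 at 180 min and 2916 at 300 min, of which 1643 rose and 1273 fell, with 17 opposite. Independent lists of these sizes would share 0.0645, 1.04, 94.9 and 803 genes. Across 12818 genes, which are not independent replicates, the covariance of both log2 fold changes was 0.293, 0.248, 0.845 and 1.59 at the 4 times. In 20 simulations of unchanged groups sharing Mock leaves it was 0.0959, 0.0865, 0.0925 and 0.1, perhaps too low where a Mock library stood apart. The correlation was 0.67, 0.51, 0.7 and 0.75 against 0.52, 0.5, 0.51 and 0.53. Without the 4 libraries 1, 20, 675 and 2551 genes were shared. The covariance at 60 min was then 0.116, against 0.147 simulated. With Mock libraries not shared between the elicitors (6 choices, an alternative chosen after the data were seen), the medians were 0, 0, 120.5 and 1376 shared genes and a covariance of 0.142, 0.217, 0.826 and 1.57.

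Mock leaves were compared with untouched leaves to measure what infiltration and the time of day did by themselves. At 120 min the secreted ribonuclease gene RNS1 (AT2G02990) rose by 6.27 ± 0.66 (adjusted p = 3.64e-09, 176 ± 76.3 against 4.57 ± 12 CPM), ERF53 (AT2G20880) by 5.92 ± 0.66 and the small heat shock gene HSP17.6A (AT5G12030) by 5.83 ± 0.7. The chalcone synthase gene TT4 fell with a log2 fold change of -5.03 ± 0.92 (adjusted p = 9.93e-05). At 180 min RNS1 rose by 6.29 ± 0.66, GA20OX3 by 5.73 ± 0.58 and AT4G33467 by 5.26 ± 1.31 (with the 4 libraries left out, RNS1 by 9.05 and 9.08 at 120 and 180 min and AT4G33467 by 7.33), and LHY fell by 4.49 ± 0.89 (adjusted p = 0.000554, 11.9 ± 2.79 against 273 ± 111 CPM). Of 11 heat shock genes 9 rose at 120 min (11 adjusted over the list alone, median 2.84, adjusted p = 2.23e-08, adjusted p = 0.789 with an estimated correlation), HSP90.1 by 2.84 ± 0.48. Of 14 endoplasmic reticulum chaperone genes 11, 9 and 7 rose at 120, 180 and 300 min (median 1 at 120 min, adjusted p = 2.25e-06, adjusted p = 0.789 with an estimated correlation), CNX1 (AT5G61790) by 1.79 ± 0.28. The glucosinolate synthesis genes CYP79B3 (AT2G22330) and CYP83B1 (AT4G31500) fell by 3 ± 0.55 and 2.89 ± 0.49 at 120 min. Counts of rises and falls were 1463 and 122, 2297 and 1160, 1467 and 935, and 752 and 76 at the 4 times. Without the 4 libraries they were 3416 and 2459, 3580 and 2423, 2816 and 1963, and 2691 and 2260.

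Jasmonate genes rose at 60 min in Mock leaves in 12 of 22 cases with 1 fall (12 and 1 adjusted over the list alone, median 1.4, adjusted p = 0.000135, adjusted p = 0.789 with an estimated correlation). JAZ6 (AT1G72450) rose by 2.63 ± 0.42 (adjusted p = 4.86e-05) and CYP94C1 (AT2G27690) by 5.46 ± 0.76 (adjusted p = 7.51e-06), each higher in 2 of 3 experiments. Of 24 WRKY genes 10 rose then (12 adjusted over the list alone, median 1.62, adjusted p = 4.74e-05, adjusted p = 0.971 with an estimated correlation), WRKY18 (AT4G31800) by 3.69 ± 0.51 in 2 of 3 experiments. The sulfur-responsive genes LSU1 (AT3G49580) and LSU3 (AT3G49570), which are close copies, and AGD1 (AT5G61980) rose most at 60 min (4.54 ± 1.31, 3.02 ± 0.9 and 3.85 ± 1.07). EXPB1 (AT2G20750), AT3G56270 and AT1G50280 fell most (-2.19 ± 0.61, -2.12 ± 0.56 and -2.02 ± 0.57). Without Mock replicate 1 these 6 had adjusted p = 0.0613, 0.0613, 0.915, 0.224, 0.141 and 0.237. Without Mock replicate 3 LSU1, LSU3, EXPB1, AT3G56270 and AT1G50280 had 0.712, 0.663, 0.273, 0.208 and 0.295. With the 4 libraries left out all 6 passed, at 5.33, 3.63, 4.37, -4.3, -3.1 and -3.59. At 300 min the lipase gene MPL1 (AT5G14180, 3.82 ± 0.71), AT3G18930 (2.49 ± 0.44) and AT5G41590 (2.47 ± 0.5) rose most. The call of MPL1 ended without Mock replicate 1 (adjusted p = 0.0804) and that of AT5G41590 without Mock replicate 3 (adjusted p = 0.163), while without the 4 libraries both passed, at 5.81 and 3.49. At 300 min 8 of 20 clock genes rose and 0 fell (adjusted p = 0.112), and without the 4 libraries 11 rose and 7 fell (adjusted p = 0.00355), with LHY at -1.32 ± 0.7 (adjusted p = 0.309) in all libraries and -7.04 (adjusted p = 5.45e-14) without the 4. Ribosomal protein genes passed in 0 of 13 cases at 300 min (median -0.44, adjusted p = 7.74e-05, adjusted p = 0.971 with an estimated correlation), and 13 fell without the 4 libraries. Phenylpropanoid genes passed in 0 of 15 cases (median -0.69, adjusted p = 9.52e-05, adjusted p = 0.971 with an estimated correlation), and 11 fell without the 4 libraries.

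Further falls in Mock leaves, those of CAF1a (AT3G44260), MYB77 (AT3G50060) and SZF1 (AT3G55980) at 300 min (-3.79 ± 1.17, -3.5 ± 1.05 and -2.57 ± 0.78), of AT4G14819 and ERF13 (AT2G44840) at 120 min and of AT5G51190, AT3G50800 and WRKY33 at 180 min, each lost the call without any of at least 3 single libraries. Among those were all Mock libraries at 120 min for AT4G14819 (adjusted p = 0.0935, 0.0774 and 0.0872), ERF13 (0.149, 0.181 and 0.0916) and Mock replicates 1 and 3 at 300 min for CAF1a, MYB77 and SZF1 (0.42 and 0.265, 0.313 and 0.264, 0.461 and 0.224). At 180 min Mock replicates 2 and 3 were among them for AT5G51190 (0.124 and 0.0661), and Mock replicates 1, 2 and 3 for AT3G50800 (0.132, 0.198 and 0.104) and WRKY33 (0.116, 0.144 and 0.123). The remaining ones were untouched libraries of experiment 3 or, for CAF1a and MYB77, Mock replicate 2 (0.0535 and 0.0645). The count at 60 min was 305, 4012 and 145 without Mock replicates 1, 2 and 3 and 2679 without the library labelled Mock 0 min replicate 2. At 120 min it was 1398 without Mock replicate 3, at 180 min 874 and 1116 without Mock replicates 2 and 3. At 300 min it was 91, 3131 and 168 without Mock replicates 1, 2 and 3 and 1979 without the library labelled flg22 0 min replicate 2. Scaling by library sizes alone shifted the median of all genes by 0.123 at 120 min and 0.13 at 180 min, with 3180 rises and 711 falls and with 2354 and 641. The 4 untouched groups, which had received no treatment, differed in 344 genes (1742 at an unadjusted p of 0.05), and in 0 without the 4 libraries. Without single libraries this count was 733, 124 and 520 for Mock 0 min replicates 1, 2 and 3, and 538, 144 and 550 for flg22 0 min replicates 1, 2 and 3.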

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

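The tests of the 4 libraries of experiment 2 were chosen after the result was seen. An exchange of labels (Mock 0 with Mock 60 min, Mock 300 with flg22 0 min) was met by 4 of 4 libraries. They were nearest the partner's class on clock genes, which had picked them, and on all genes. Handling before harvest stays open, as its test reused the clock genes. Their correlation with the labelled class was at most 0.47 here and at least 0.93 in the others of these classes. Shallow depth is argued against, since all 4 were deeper than the shallowest remaining untouched or Mock library. No sample sheet was used, so which count is right stays open.

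For the negative interaction at 300 min, with 253 genes in all, the test without the 4 libraries was chosen after the result was seen, and the linear and plateau tests before. Without the 4 libraries 71.1% of the negative calls were kept, so these libraries alone did not make the pattern. For 319 genes chosen in 2 experiments and measured in the third, the CPM gained with Ed in flg22 leaves was 0.909 of that in Mock leaves, near what responses that add on the linear scale would give. Per gene, both elicitors stood a median 0.31 log2 above the higher single level, past the 0.3 set for a shared plateau. Without a spread, 1 experiment cannot decide this. Separate group medians were 101 (both), 50.5 (flg22) and 48 CPM (Ed). Only experiment 3 could serve there, as 0 genes passed without experiment 1 or 2, and in genes chosen by their mean Ed effect the ratio over left-out experiments 1 to 3 was 0.893, 1.02 and 1.38 where flg22 had raised them and 0.481, 0.886 and 1.35 where it had not moved them, so the cause stays open, also because the doubted Mock 300 min library enters the choice of the 319 genes and the ratios of experiment 2.

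The tests of the untouched leaves of experiment 3 were chosen after the result was seen. Touch genes stood 1.85 higher in median log2 CPM in these leaves than in those of experiments 1 and 2, with 6 of 10 above every other untouched library outside the 4 in doubt and 3 lower. Leaves handled before harvest stay open, since 5 of 10, among them TCH4 (5.5 against 4.69), stood above the Mock 60 min level, which the test had set as the upper limit. A later harvest is argued against by clock genes nearest the untouched class in 4 of 4 libraries, and shallow depth by the 2 of these libraries that were deeper than the shallowest of experiments 1 and 2. Anything else specific to experiment 3 is open too.

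Splits of the libraries into other groups were set before the results were seen. For flg22 against Mock, 1 of 10 splits, the real one, called as many genes at 60, 120, 180 and 300 min (real 1650, 1716, 3723 and 6723, highest other 1, 17, 2 and 270). For Ed against Mock these were 1, 2, 1 and 1 of 10 (highest other 0, 108, 0 and 24). For flg22+Ed against Mock they were 1, 1, 1 and 1 of 10 (highest other 0, 67, 52 and 312), and for flg22+Ed against flg22 10, 1, 1 and 1 of 10 (highest other 1, 0, 0 and 0). These 10 splits are too few for a share under 0.05, as are the 4 that swap libraries within experiments, of which only the real one reached its count (highest other 17 for flg22 at 120 min, 24 for Ed at 300 min and 0 elsewhere) save at 60 min for flg22+Ed against flg22, where all 4 gave 0. For the interaction, 60, 60, 12 and 14 of 60 splits called at least as many genes as the real 0, 0, 1 and 253 (highest other 1064, 2827, 3598 and 8778). Such splits mix the treatment effects, so their high counts point to that structure of the samples. For Mock against untouched leaves it was 4, 2, 1 and 7 of 60 splits (real 1585, 3457, 2402 and 828, highest other 2231, 4719, 851 and 1414), and for the untouched groups 48 of 60 (real 344, highest other 1318). Within experiments, Mock against untouched leaves gave 3, 1, 1 and 3 of 20 (highest other 2052, 704, 362 and 1376), the interaction 20, 20, 9 and 5 of 20 (highest other 0, 726, 5873 and 4854) and the untouched groups 11 of 20 (highest other 458), and 20 splits are too few for a share under 0.05.

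Between 60 and 300 min 1088 genes changed in their response to flg22, 805 in that to Ed and 4695 in that to both. The doubted Mock libraries of experiment 2 enter these, and without the 4 libraries they were 1728, 1214 and 5579. Leaving out experiments 1, 2 and 3 gave 234, 314 and 125 for flg22, 0, 595 and 668 for Ed and 1901, 4108 and 2882 for both, and library sizes alone turned 541 rises and 547 falls for flg22 into 1162 and 190. For the interaction at 180 min 1 gene passed. Between the flg22 and Ed responses, the shared Mock libraries alone did not make the covariance at 180 and 300 min, which was 0.666 to 1.02 and 1.35 to 1.65 over 6 choices of Mock libraries not shared. At 60 and 120 min it was -0.0787 to 0.488 and -0.223 to 0.454, so a contribution of sharing stays open there.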

How the results depend on the processing

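Counts by comparison are given at the named times, and the cause of a move was not tested. Without the 4 libraries, flg22 against Mock gave 830 at 60 min and 2779 at 120 min, flg22+Ed against Mock 496 and 3800, flg22+Ed against flg22 3545 at 300 min, the interaction 53 at 180 min, Mock against untouched 5875, 6003, 4779 and 4951, the untouched groups 0 and the overlap at 120 min 20. With a replicate block as well, flg22 at 120 min gave 3299, Ed 60, flg22+Ed 4274, flg22+Ed against flg22 5, 200 and 4259 from 120 min on, the interaction 111 and 428 at 180 and 300 min, Mock against untouched 6345, 6499, 5226 and 5349, and the untouched groups 0.

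With only the groups compared, flg22 gave 702 and flg22+Ed 354 at 60 min, Ed 0 at 120 min, flg22+Ed against flg22 0 and 168 at 120 and 180 min, the interaction 135 and 693 at 180 and 300 min, Mock against untouched 0, 1950, 1087 and 0, and the untouched groups 0. With a replicate block alone, Ed at 120 min gave 40, flg22+Ed against flg22 at 180 min 135, the interaction at 180 min 31 and the overlap at 120 min 34, and it moved no other count by more than 1.5 times. RLE factors gave 8 for Ed and 7 for the overlap at 120 min. For the interaction at 180 min library sizes alone gave 14 and no filter 14. Limma-voom gave 2 for Ed and 0 for flg22+Ed against flg22 at 120 min, 141 for the latter at 180 min, 0 for the interaction at 180 min, 671 for Mock against untouched at 60 min and 0 for the untouched groups. DESeq2 gave 6 and 38 for Ed at 60 and 120 min, 4 for flg22+Ed against flg22 at 120 min, 1 and 39 for the interaction at 60 and 180 min, 555 for the untouched groups and 4 and 30 for the overlap at 60 and 120 min. Without the untouched libraries of experiment 3, Mock against untouched gave 1564 at 180 min and 472 at 300 min and the untouched groups 577.

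Over 23 lists and 4 times, list tests that passed numbered 42, 47, 49, 27, 31 and 17 in the 6 comparisons. With an estimated correlation they numbered 1, 2, 0, 1, 1 and 0, so most list calls rest on the preset correlation. Fry gave 28 for Ed, 8 for flg22+Ed against flg22, 3 for the interaction and 9 for Mock against untouched. The Ed effect with minus without flg22 was -0.0931, 0.182 and 0.175 on the linear scale at 60, 120 and 180 min, -1.4 and -0.474 with prior counts of 0.5 and 5 at 120 min, and -0.704 at 300 min over genes with a mean effect of at least 1. The flg22 effect was 0.00127 on the linear scale at 120 min, -0.712, -0.185, -0.343 and -0.209 at the 4 times over genes with a mean effect of at least 1, and -0.163 and -0.223 at 120 and 180 min over genes chosen in the other 2 experiments.

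Leaving out 1 library or experiment gave 114 to 2239, 145 to 2385 and 1752 to 3756 for flg22 at 60, 120 and 180 min, 0 to 1, 0 to 56, 0 to 753 and 1257 to 3974 for Ed, and 97 to 1788, 833 to 2906 and 3330 to 5568 for flg22+Ed at 60, 120 and 180 min. It gave 0 to 9, 3 to 120 and 500 to 2097 for flg22+Ed against flg22 from 120 min on, 0 to 22, 0 to 55 and 0 to 332 for the interaction, and 0 to 5211, 660 to 4539, 339 to 3449 and 0 to 4492 for Mock against untouched. The untouched groups ranged from 0 to 733, the overlap from 0 to 0, 0 to 50, 0 to 504 and 779 to 2390, the Ed effect from -3.43 to -0.515 at 120 min and -0.464 to -0.2 at 300 min, and the flg22 effect from -0.638 to -0.428, -0.438 to 0.228, -0.205 to 0.0275 and -0.217 to -0.0628 at the 4 times, with genes chosen anew in each fit. With Mock libraries not shared the overlap was 0, 0, 120.5 and 1376.

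Of 438 values of named genes, 241 passed, of which 143 kept direction and call in every alternative, 98 lost the call in at least 1, and 4 values reversed. LHY reversed at 300 min, to 0.28 for flg22 and 0.65 for Ed without experiment 2 and to 0.24 and 0.54 without the 4 libraries, with lowest values of -5.84 for flg22 without experiment 1 and -5.67 for Ed without experiment 3. Depth, at 1.46 M counts in the shallowest library, limits genes under about 2.06 CPM, where 3 counts or fewer were seen.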

Other observations

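Cytosolic ribosomal protein genes were called differently with and without the 4 libraries of experiment 2. In Mock against untouched leaves, 0 of 13 passed at 300 min and 13 fell without the 4 libraries, which were chosen after the result was seen. RPL4A stood at -0.49 with an adjusted p of 0.263, and at -1.17 with an adjusted p of 2.17e-05 without them.

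The series title asks how both forms of immunity interact. EDS5, PAD3 and FMO1 rose when Ed was added to flg22 at 300 min and did not pass with flg22 alone, and PBS3 rose in both cases, by 2.61 ± 0.69 with flg22 alone (adjusted p = 0.0022). FRK1, CYP81F2 and BIP2 did not pass when Ed was added. The negative interactions may reflect responses that add on the linear scale, given the ratio of 0.909 in 1 experiment. The sample sheet of experiment 2 could settle the labels of the 4 libraries.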
